A study of Mus musculus with 20 samples.

How the data were processed

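RNA of mouse white adipose tissue was sequenced in 20 libraries from 4 groups of 5 mice, which received chow or a high-fat diet together with water or a water extract of Tibetan tea for 10 weeks. Per the labels' protocols, total RNA was isolated with TRIzol, passed a quality screen and entered a stranded poly-A library kit from Illumina. The adipose depot, the sex of the mice and the hour of collection are not given in the sources used here. By the design text the mice of a group are separate animals, so the p-values measure the spread between mice together with that of tissue sampling and library preparation.

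The authors deposited 1 table per library with whole-number counts of reads per gene, not normalized. Per the submitters' processing notes, fastp 0.23.2, HISAT2 2.2.1 and featureCounts 2.0.6 were used. Per the file headers, featureCounts 2.0.6 ran on the GENCODE vM32 annotation of GRCm39, counted at exons and summed by gene name. The submitters' processing notes name mm10 instead, and the coordinates in the count tables belong to GRCm39, so all positions printed here are GRCm39, counted from 1. Alignment settings and the treatment of reads with several matches are not given in the sources used here.

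Some of these settings bear on the values. Per the file headers, the paired option was set without the option that counts pairs as 1 fragment. Among counts from 1 to 20, between 68.1% and 72.2% were even numbers in each library, so that most fragments entered as 2 reads and the counts overstate the number of independent fragments. Per the file headers, no strand option was given although the kit keeps strand, so reads of a gene and of a partner on the opposite strand cannot be told apart. Of 113 genes named in the text, 25 have exonic bases that overlap another annotated gene, 21 of them a gene on the opposite strand, and 3 overlap over more than 20% of their exonic bases. Stearoyl-CoA desaturases, antigen presentation genes, pheromone receptors, digestive enzymes and other families of near-identical copies can exchange reads, so their values are less certain.

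Each table held 56805 genes, with no duplicated name and 0 entries without a gene. The total was 53047057 to 93314761 reads in genes per library, spread over 23800 to 27826 genes with at least 1 read. This depth limits the precision of genes with few reads, and for all others the spread between mice was the larger part of the error. Over 40 pairs of libraries within groups, the lowest chi-square statistic per gene was 68.7, so no pair agreed within sampling noise and no library was counted as a repeat of another.

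From the deposited counts, genes with low values were removed with the filterByExpr function of edgeR 4.0.16 (at least 10 counts at the median library size in 5 libraries, and at least 15 in total), which left 21306 genes and removed 35499. Library sizes were scaled by trimmed means of M values (TMM). The edgeR quasi-likelihood F test (estimateDisp, glmQLFit, glmQLFTest, in R 4.3.3) was fitted to group means over all 20 libraries, with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested. A gene was called at an adjusted p below 0.05. The common biological coefficient of variation was 0.593. Levels are CPM as edgeR computes them on the TMM-scaled library size, as mean ± SD over 5 libraries, and standard errors (SE) of log2 fold changes were derived from the fold change and its F statistic.

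The design implies 5 comparisons, namely high-fat against chow feeding in water-drinking mice, tea against water in high-fat-fed mice, tea against water in chow-fed mice, high-fat against chow feeding in tea-drinking mice, and the interaction of diet and tea. Of 52 gene lists, 51 had at least 5 tested genes. The lists of pathways, cell types and other tissues were written before the data were examined, and those described were picked after their tests were seen. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, with camera at an estimated correlation and with fry.

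Named genes followed a rule fixed before the data were examined. Per comparison it takes up to 5 called genes with the largest rise and 5 with the largest fall, at a mean log2 CPM of at least 1, with a symbol that is not a predicted-gene name, and whose libraries do not overlap between the groups (overlap was not asked of the interaction). It adds up to 3 members with the lowest p of each list described, and 12 genes named in every comparison whatever their result. Values of 1 gene that the rule takes are not reported here, while it stays in the counts and lists. Any other gene named is marked as chosen after its values were seen.

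The same steps were tested on simulated counts drawn from the real libraries' means and sizes, with 200 genes changed. At a simulated fold of 2 the share of changed genes recovered was 14.9% for diet in water, 29.9% for tea in high-fat feeding, 31.3% for tea in chow, 25.4% for diet in tea and 3% for the interaction. At a fold of 4 these shares were 51.5%, 53%, 60.6%, 56.1% and 48.5%, and at a fold of 1.5 they were 7.5%, 3%, 1.5%, 6% and 0%. False calls made up 2%, 9%, 2.9%, 1.6% and 2.7% of all calls, with 20931, 20914, 20909, 20917 and 20907 genes tested. The shifted list ranked 1 in each comparison.

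Alternatives fixed before the data were examined were other scaling factors, other filters, DESeq2 1.42.0, limma voom with sample weights, a fit on only the groups compared, the replicate number as a block, 1 surrogate variable from sva 3.50.0, other thresholds and the omission of each library in turn. Chosen after seeing the data were fits without 2, 3 or 9 libraries that held transcripts of other tissues, levels of 3 other-tissue lists as covariates, and counts divided by 2 and rounded. No library was left out of the values reported unless a sentence says so.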

Results

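White adipose tissue was profiled by RNA sequencing in 20 mice, 5 in each of 4 groups that received chow or a high-fat diet and drank water or a water extract of Tibetan tea, a fermented dark tea, for 10 weeks. The libraries held 53047057 to 93314761 reads in genes. Of 56805 annotated genes, 21306 had enough reads to be tested. The gene lists described were picked after their tests were seen, from lists written before the data were examined.

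Some libraries held transcripts of other organs. In chow water replicate 1, 34.1% of reads fell in genes of the pancreas acinus list, with Pnlip, a pancreatic lipase, at 95800 CPM and Ctrb1, a chymotrypsinogen, at 83830 CPM, against at most 5.95 CPM of Pnlip in any other library. In high-fat tea replicate 4, 2.32% of reads fell in the kidney list, with Kap at 14010 CPM. The list took 0.175% of reads in chow water replicate 2. In high-fat water replicate 4, Svs5, a seminal vesicle protein, reached 18850 CPM and Star, a steroid synthesis gene of the adrenal cortex, reached 5753 CPM, and the epididymis and testis list took 3.14% of reads. These 5 genes were named after their values were seen. Skeletal muscle genes took 3.38% of reads in high-fat water replicate 5, 3.72% in high-fat tea replicate 1, and between 0.49% and 0.97% in chow water replicate 2, chow tea replicate 1, high-fat water replicate 3 and high-fat tea replicate 3. In all, 9 libraries held over 1000 CPM of such a list. The first principal component (28.2% of the variance) set chow water replicate 1 (−181.9) and high-fat tea replicate 4 (−185.7) apart, and on the second (13.7%) the 5 high-fat water libraries lay between 54.9 and 102.

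**Figure D1:**
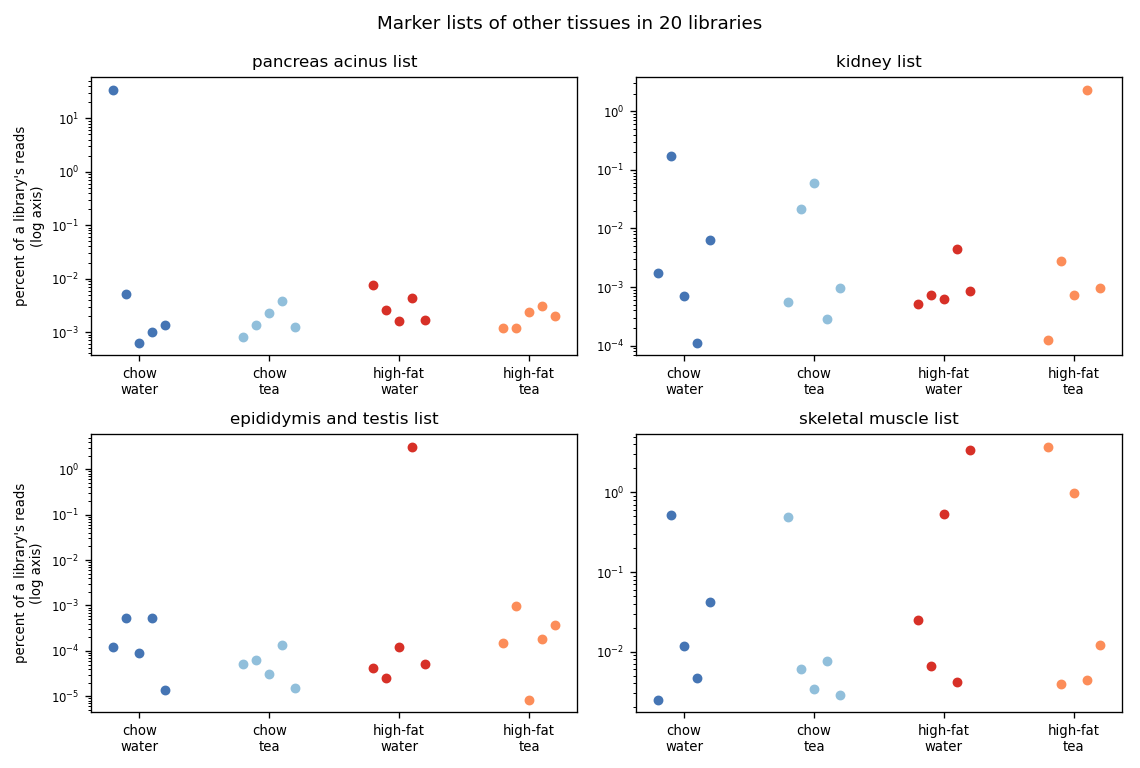
Share of each library's reads in genes of 4 other-tissue lists (percent of reads in genes, log axis), by group. Dots are single libraries. Chow water replicate 1 stands at 34.1% for the pancreas list and high-fat tea replicate 4 at 2.32% for the kidney list.

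The comparison of high-fat with chow feeding in water-drinking mice compares the diets without tea. Transcripts of leptin and of lipid-associated macrophages were higher after the high-fat diet. Lep, the hormone leptin (chromosome 6, 29060219 to 29073876, plus strand), rose from 58.9 ± 64.3 to 1608 ± 867 CPM (SD, n = 5 per group), a 27.3-fold change (log2 4.77, SE 1.18, adjusted p = 0.0128; 5.69 without chow water replicate 5). Trem2, a lipid receptor of macrophages (chromosome 17, 48653429 to 48661175, plus strand), rose from 2.84 ± 1.07 to 47.0 ± 30.9 CPM (log2 4.04, SE 0.62, adjusted p = 0.000758). Mmp12, macrophage elastase (chromosome 9, 7344381 to 7369499, plus strand), rose from 0.869 ± 0.076 to 153 ± 80.1 CPM (log2 7.45, SE 0.99, adjusted p = 0.000279). In the lipid-associated macrophage list, 12 of 20 members rose and 0 fell (13 and 0 adjusted over the list alone), among them Atp6v0d2, a proton pump subunit (log2 5.07, SE 0.84; 5.75 without chow water replicate 2). The list's median log2 change was 1.23 and it was called by camera (adjusted p = 9.62e-08), but not with an estimated correlation (adjusted p = 0.382 with an estimated correlation). Of the general macrophage list, 5 of 20 members rose and 2 fell (7 and 3 adjusted over the list alone), and the list was not called (median 0.46, adjusted p = 0.117), although it was without any one of chow water replicate 3 and high-fat water replicates 4 and 5. Itgax, an integrin of macrophages and dendritic cells, rose by 3.20 on the log2 scale (SE 0.74), and by 4.40 without chow water replicate 1. Ccl2, a monocyte chemokine, rose by 2.01 (SE 0.59, adjusted p = 0.0301), a call that ended without any one of chow water replicates 1, 2, 3 and 4 and high-fat water replicate 1. Tnf and Col1a1 were not called (log2 1.26, adjusted p = 0.244, at 0.65 without high-fat water replicate 1, and log2 0.83, adjusted p = 0.128). Adgre1 (log2 1.51, SE 0.41, adjusted p = 0.0206) lost its call without chow water replicate 2 or high-fat water replicate 1 (log2 from 1.23 to 1.77 over the libraries left out in turn).

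Genes of antigen presentation and of the matrix rose with them. Ctss, the protease cathepsin S (log2 2.08, SE 0.35), Ciita, the master regulator of class II genes (log2 1.47, SE 0.31), and H2-DMb1 (log2 1.41, SE 0.30) were among 8 of 11 class II genes that rose, with 0 that fell (8 and 0 adjusted over the list alone; adjusted p = 2.8e-05 by camera, adjusted p = 0.74 with an estimated correlation). Of 27 matrix and fibrosis genes 10 rose and 0 fell (11 and 0 adjusted over the list alone; adjusted p = 1.69e-06, adjusted p = 0.74 with an estimated correlation). Col15a1, a basement membrane collagen (chromosome 4, 47208161 to 47313167, plus strand), went from 56.8 ± 26.4 to 391.7 ± 98.7 CPM (log2 2.79, SE 0.42, adjusted p = 0.000702), and Col6a2 rose by 1.85 (SE 0.39). Timp1, a protease inhibitor, rose by 2.23 (SE 0.46), and by 1.49 without high-fat water replicate 4. Further called genes with large rises were Itgad, an integrin (log2 8.35, SE 1.60), Tph2, a serotonin synthesis enzyme (log2 8.32, SE 1.69), Vsig8 (log2 6.78, SE 1.19) and Lipf, a lipase (log2 5.66, SE 0.97). Without high-fat water replicate 1 the values of Itgad and Tph2 were 6.88 and 6.82, and that of Tph2 was 9.29 without chow water replicate 4.

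Genes of drug metabolism, amino acid breakdown and glucocorticoid response fell. Cyp2d22, a cytochrome P450 (chromosome 15, 82254728 to 82264461, minus strand), fell from 168.4 ± 44.0 to 45.7 ± 6.79 CPM (log2 −1.88, SE 0.22, adjusted p = 0.000122), and Cyp2e1, another, from 6486 ± 2523 to 1372 ± 534.9 CPM (log2 −2.24, SE 0.42, adjusted p = 0.00284). In the aryl hydrocarbon receptor and drug metabolism list 11 of 21 members fell and 0 rose (13 and 0 adjusted over the list alone), with a median of −0.85. It was the 1 list of 51 called both by camera (adjusted p = 8.52e-07) and with an estimated correlation (adjusted p = 0.00981 with an estimated correlation). The members that moved included Fmo1, a monooxygenase (log2 −1.50, SE 0.29). Of 19 genes of branched-chain amino acid breakdown 11 fell (12 adjusted over the list alone; adjusted p = 1.58e-06, adjusted p = 0.74 with an estimated correlation), with Hsd17b10 at −1.65 (SE 0.28) and Aldh6a1 at −1.02 (SE 0.23). Of 15 glucocorticoid response genes 7 fell (8 adjusted over the list alone; adjusted p = 8.31e-06, adjusted p = 0.382 with an estimated correlation), with Cdkn1a, a cell-cycle inhibitor, at −2.51 (SE 0.39) and Fkbp5, a chaperone of the receptor, at −1.86 (SE 0.30). Nuclear genes of oxidative phosphorylation had a median of −0.44, with 3 of 44 called lower (1 adjusted over the list alone; adjusted p = 4.32e-06, adjusted p = 0.768 with an estimated correlation), such as Atp5c1 (log2 −0.71, SE 0.17). Fatty acid oxidation genes had a median of −0.41 with 4 of 27 called lower (2 adjusted over the list alone; adjusted p = 0.00677, adjusted p = 0.768 with an estimated correlation), and the list's call ended without chow water replicate 4.

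Lipogenic, adipokine and clock genes moved in both directions. Scd2, a desaturase whose reads can be shared with Scd1 and Scd3 (chromosome 19, 44282113 to 44295303, plus strand), rose from 47.3 ± 16.1 to 324.3 ± 82.2 CPM (log2 2.78, SE 0.26, adjusted p = 9.13e-06), and Pgd, an enzyme of the pentose phosphate pathway, rose by 0.78 (SE 0.18). Acacb, an acetyl-CoA carboxylase, fell by 2.14 on the log2 scale (SE 0.43). In de novo lipogenesis 3 of 19 rose and 3 fell (4 and 3 adjusted over the list alone; adjusted p = 0.825), and Fasn (log2 −1.51, adjusted p = 0.175, at −0.68 without chow water replicate 4) and Scd1 (log2 −0.69, adjusted p = 0.446) were not called. Among 18 adipokines 6 rose and 1 fell (7 and 4 adjusted over the list alone; adjusted p = 0.117), with Sfrp5, a Wnt antagonist, at 3.86 (SE 0.67), Npr3, a natriuretic peptide receptor, at 2.99 (SE 0.62) and Cfd, adipsin, at −2.35 (SE 0.50). Adipoq (log2 0.11, adjusted p = 0.87), Pparg (log2 −0.63, adjusted p = 0.209) and Ucp1 (log2 0.94, adjusted p = 0.738, at 1.66 without chow water replicate 4) were not called. In the circadian clock list 9 of 18 rose and 5 fell (11 and 6 adjusted over the list alone). Dbp, an output gene of the clock (chromosome 7, 45354512 to 45359627, plus strand), rose from 2.77 ± 0.687 to 68.3 ± 13.4 CPM (log2 4.62, SE 0.23, adjusted p = 2.15e-09), while Npas2, a partner of the core activator (chromosome 1, 39232812 to 39402317, plus strand), fell from 26.9 ± 4.43 to 1.07 ± 0.586 CPM (log2 −4.65, SE 0.37, adjusted p = 1.71e-06). Of the exonic bases of Dbp, 18% overlap Sphk2 on the opposite strand. The list's camera call (adjusted p = 0.0406, adjusted p = 0.74 with an estimated correlation) ended with only the groups compared, without 2, 3 or 9 of the libraries with other-tissue transcripts, with other-tissue covariates, and without any one of chow water replicates 1 and 5 and high-fat water replicates 3 and 5.

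Other-tissue genes were called lower too. All 12 tested pancreas acinus genes fell (median −13.65; 12 adjusted over the list alone; adjusted p = 0.0236, adjusted p = 0.768 with an estimated correlation), and so did all 7 intestine genes (7 adjusted over the list alone; adjusted p = 0.00506, adjusted p = 0.74 with an estimated correlation). Both lists were highest in chow water replicate 1, where the intestine list took 0.295% of reads, and without that library the pancreas median was −0.52 and its call ended, while the intestine median went from −10.47 to −2.93 and stayed called. The pancreas median was −16.05 without high-fat water replicate 1. Btnl6, Pigr and Guca2b, with changes of −7.66, −7.77 and −7.76 and adjusted p of 0.00638, 0.0183 and 0.025, were at −1.97, −2.60 and −3.80 without that library, and the calls of Pigr and Guca2b ended. Pigr stood at −8.50 without high-fat water replicate 4 and also lost its call without high-fat water replicate 1. Gsta2 (−6.98) and Cyp4a10 (−6.59) were highest in chow water replicate 2 among the water libraries, and stood at −4.10 and −4.52 without it, no longer called. The calls of Gsta2, Cyp4a10 and Guca2b ended in 7, 6 and 5 of the 10 fits without a library. Those of Gsta2 and Cyp4a10 ended without any one of the 5 high-fat water libraries. Over all 20 libraries both genes were highest in high-fat tea replicate 4 (121.7 and 835.1 CPM), which also had the highest kidney share, and chow water replicate 2 was second in both genes and in that share. The kidney list was not called (median −5.06, adjusted p = 0.107), nor the skeletal muscle list (median 2.96, adjusted p = 0.102).

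By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3232 of 21306 genes were called, 1718 higher and 1514 lower on the high-fat diet, and 6569 had an unadjusted p below 0.05, where chance gives 1065. The 5 libraries of one group did not overlap the 5 of the other in 2753 genes (12.9%), where chance gives 0.79%. The count was 4546 without 3 libraries with other-organ transcripts (2708 genes shared with the 3232) and 2052 without 9, settings chosen after seeing the data. It was 1890 without high-fat water replicate 1 and 2110 without chow water replicate 2, and 5333 with limma voom. Of 66 calls of genes that the naming rule takes, 19 ended without at least 1 library, 14 of them without high-fat water replicate 1.

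**Figure D2:**
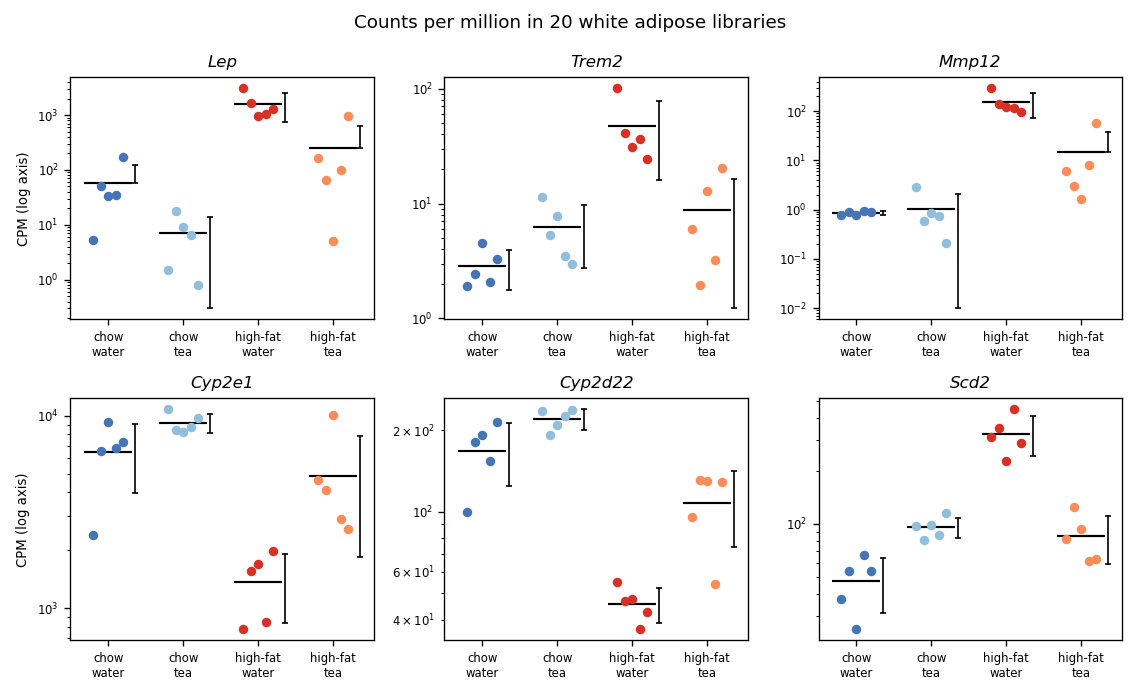
Levels of 6 genes named in the text (CPM, log axis) in the 4 groups. Dots are single libraries, the horizontal line is the mean of 5, and the bar at the right is the SD, whose lower arm is left out where it would reach 0 or below. Scd2 stood at 324.3 ± 82.2 CPM in high-fat water libraries and 84.8 ± 26.1 CPM in high-fat tea libraries.

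The comparison of tea with water in high-fat-fed mice is the one the series title names. Some lipid-associated macrophage, antigen presentation and matrix genes fell with tea, and some drug metabolism genes rose. Lgals3, galectin-3, fell from 420.9 ± 288.9 to 88.7 ± 65.8 CPM (n = 5 per group, log2 −2.25, SE 0.43, adjusted p = 0.0112), and Ctss from 296.1 ± 138.8 to 82.2 ± 44.3 CPM (log2 −1.85, SE 0.35, adjusted p = 0.0108). Col15a1 fell from 391.7 ± 98.7 to 75.1 ± 52.7 CPM (log2 −2.38, SE 0.42, adjusted p = 0.00713). Cyp2d22 rose from 45.7 ± 6.79 to 108.3 ± 33.9 CPM (log2 1.24, SE 0.22, adjusted p = 0.00746) and Fmo1 from 142.3 ± 35.6 to 385.5 ± 144.9 CPM (log2 1.44, SE 0.29, adjusted p = 0.0141). Scd2 fell from 324.3 ± 82.2 to 84.8 ± 26.1 CPM (log2 −1.94, SE 0.25, adjusted p = 0.000928). These 6 genes stayed called whichever library was left out. With only the groups compared, Scd2 stayed called (adjusted p = 0.0239), and the adjusted p of the others was 0.0783, 0.0699, 0.0658, 0.0643 and 0.0699.

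Lipid-associated macrophage genes were called lower in 6 of 20 cases and higher in 0 (11 and 1 adjusted over the list alone; median −0.88, adjusted p = 5.94e-08, adjusted p = 0.37 with an estimated correlation). Trem2 fell from 47.0 ± 30.9 to 8.85 ± 7.63 CPM (log2 −2.41, SE 0.58, adjusted p = 0.0277), Gpnmb, a lysosomal glycoprotein of foamy macrophages, from 422.4 ± 250.8 to 75.1 ± 84.0 CPM (log2 −2.49, SE 0.56, adjusted p = 0.0212) and Mmp12 from 153 ± 80.1 to 15.2 ± 23.4 CPM (log2 −3.33, SE 0.81, adjusted p = 0.0289). The calls of Trem2, Gpnmb and Mmp12 each ended without high-fat water replicate 1 or high-fat tea replicates 2 or 3, and those of Trem2 and Mmp12 also without high-fat water replicate 2 or high-fat tea replicate 1, and that of Mmp12 without high-fat tea replicate 4. Over the libraries left out in turn, their log2 changes ranged from −2.97 to −1.92, from −3.47 to −2.05 and from −5.01 to −2.96. Itgax (log2 −2.70, SE 0.72, adjusted p = 0.0424) lost its call whichever library was left out, except high-fat water replicate 5 and high-fat tea replicate 5, and stood at −3.67 without the latter. The general macrophage list was not called (0 of 20 members called, 2 lower adjusted over the list alone; median −0.33, adjusted p = 0.0546), although it was without any one of high-fat water replicates 4 and 5 and high-fat tea replicates 3 and 5. Adgre1 (adjusted p = 0.0564), Ccl2 (adjusted p = 0.224), Tnf (log2 −1.40, adjusted p = 0.246; −0.79 without high-fat water replicate 1) and Col1a1 (log2 −0.82, adjusted p = 0.179) were not called, although Adgre1 was without high-fat tea replicate 5 (log2 −1.79, adjusted p = 0.0137). Lep stood at 255.4 ± 388.5 CPM with tea against 1608 ± 867 CPM with water, which missed the threshold (log2 −2.65, SE 1.07, adjusted p = 0.144) although no tea library reached the lowest water library. High-fat tea replicate 5 held 942.7 CPM of Lep, and without it the change was −4.27 and called.

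Of 11 class II genes 6 fell and 0 rose (9 and 0 adjusted over the list alone; adjusted p = 1.24e-08, adjusted p = 0.37 with an estimated correlation), and of 27 matrix genes 5 fell and 0 rose (11 and 0 adjusted over the list alone; adjusted p = 1.15e-10, adjusted p = 0.516 with an estimated correlation). Ciita (log2 −1.42, SE 0.31), H2-DMb1 (log2 −1.40, SE 0.30) and Col6a2 (log2 −1.66, SE 0.38) were among them, and their calls, too, ended without high-fat water replicate 1, those of Ciita and Col6a2 also without high-fat water replicate 2 or high-fat tea replicate 3, and that of Col6a2 without high-fat tea replicate 2. Ubd, a ubiquitin-like modifier, fell from 68.8 ± 66.8 to 7.15 ± 5.74 CPM (log2 −3.27, SE 0.58, adjusted p = 0.00779), by 2.47 without high-fat water replicate 1 and by 3.88 without high-fat tea replicate 5. Oxtr (log2 −3.38, adjusted p = 0.0234), Saa3 (log2 −3.18, adjusted p = 0.0418) and Tph2 (log2 −5.98, adjusted p = 0.0324) fell as well, and none of these 3 stayed called without high-fat water replicate 1 (log2 −2.87, −2.02 and −4.47) or without high-fat tea replicate 2 or 3. Without high-fat tea replicate 5, Oxtr stood at −4.45 and Tph2 at −8.84. The calls of Saa3 and Tph2 also ended without high-fat water replicate 2 or high-fat tea replicate 1 or 4, and that of Saa3 without high-fat water replicate 3 or high-fat tea replicate 5.

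In the aryl hydrocarbon receptor and drug metabolism list 8 of 21 members rose and 0 fell (12 and 1 adjusted over the list alone). Its median was 0.71 and it was called by camera (adjusted p = 7.83e-06) and with an estimated correlation (adjusted p = 0.0219 with an estimated correlation). Ces1f, a carboxylesterase, rose by 1.93 (SE 0.40, adjusted p = 0.0161), was highest in high-fat tea replicate 4, the library with kidney transcripts, and stood at 1.23 without it. Its call ended without high-fat water replicate 1. Of 19 genes of branched-chain amino acid breakdown 8 rose and 0 fell (12 and 0 adjusted over the list alone; adjusted p = 1.72e-09, adjusted p = 0.37 with an estimated correlation), with Hsd17b10 at 1.26 (SE 0.28) and Ppm1k, the phosphatase that activates the pathway, at 0.91 (SE 0.19). Both calls ended without high-fat water replicate 1 or high-fat tea replicate 3, and that of Hsd17b10 also without high-fat water replicate 2 or high-fat tea replicate 2, with log2 changes of at least 0.89 for Hsd17b10 and 0.77 for Ppm1k. None of 44 oxidative phosphorylation genes was called (0 adjusted over the list alone), while their median of 0.43 gave a camera adjusted p of 1.51e-07 (adjusted p = 0.712 with an estimated correlation). In the same comparison mitochondrially encoded transcripts were higher (median 0.69, 0 of 13 called, 0 adjusted over the list alone; adjusted p = 0.00242, adjusted p = 0.712 with an estimated correlation), and so were mesothelial cell genes (median 0.74, 12 of 12 positive, 0 called, 1 adjusted over the list alone; adjusted p = 0.00639, adjusted p = 0.712 with an estimated correlation). Both calls stayed whichever library was left out. With diet in water the mesothelial genes were lower (median −0.52, 3 of 12 called, 4 adjusted over the list alone; adjusted p = 0.046, adjusted p = 0.768 with an estimated correlation), a call that ended in 5 of 10 fits without a library. The thermogenic list was not called (median 0.36, adjusted p = 0.267).

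In de novo lipogenesis 1 of 19 genes rose and 2 fell (3 and 3 adjusted over the list alone; adjusted p = 0.155), with Acacb at 1.94 (SE 0.43) and Pgd at −0.79 (SE 0.18), calls that ended without high-fat water replicates 1 or 2 or high-fat tea replicates 2 or 3. Of 24 cholesterol synthesis genes 3 fell (4 adjusted over the list alone), among them Sc5d, a sterol desaturase, from 134.4 ± 18.5 to 67.0 ± 9.56 CPM (log2 −1, SE 0.14, adjusted p = 0.0022). The list's median was −0.23 and its mean −0.015 (adjusted p = 0.0217, adjusted p = 0.712 with an estimated correlation), and its call ended without high-fat tea replicate 1, 3 or 5. Of 18 clock genes 1 was called (1 adjusted over the list alone), and the list was not called (median 0.17, adjusted p = 0.0961). Adipoq (log2 −0.19, adjusted p = 0.813), Pparg (log2 0.26, adjusted p = 0.693), Scd1 (log2 −0.12, adjusted p = 0.934), Fasn (log2 −0.23, adjusted p = 0.891) and Ucp1 (log2 −1.11, adjusted p = 0.736) were not called. Without high-fat tea replicate 2 the last 2 stood at −1.52 and −1.76.

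The largest rises with tea (log2, adjusted p) were Wfdc2 (7.84, 0.0292), Acot3, an acyl-CoA thioesterase (6.38, 0.0141), and Scnn1g, a sodium channel subunit (5.84, 0.014). Rdh16, a retinol dehydrogenase (5.63, 0.0424), and Glt1d1 (5.56, 0.00478) followed. All 5 were highest in high-fat tea replicate 4. Without it they stood, in this order, at 6.92, 3.92, 4.13, 1.20 (Rdh16, not called) and 4.50. Wfdc2 was also high in chow water replicates 2 and 4 (22.1 and 28.6 CPM), as was Scnn1g (7.86 and 6.14 CPM). The calls of Wfdc2 and Rdh16 also ended without any one of the 5 high-fat water libraries or high-fat tea replicate 2, and that of Rdh16 without high-fat tea replicate 3. The 10 tested kidney genes had a median of 8.67, with 0 called (10 adjusted over the list alone; adjusted p = 0.0579). Without high-fat tea replicate 4 the median was 0.24, and without high-fat water replicate 4 it was 10.51. Without any one of high-fat tea replicates 1, 2, 3 and 5 the list was called.

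By edgeR's quasi-likelihood test 928 genes were called, 439 higher and 489 lower with tea, and 5035 had an unadjusted p below 0.05. The libraries of the groups did not overlap in 1182 genes (5.55%, where chance gives 0.79%). The count depended on the libraries and on the test used. With only the groups compared it was 21 (20 of them among the 928), and DESeq2 called 2444 and limma voom 2011. It was 1602 without 3 libraries with other-organ transcripts (751 shared) and 13 without 9, settings chosen after seeing the data. Left out in turn, high-fat water replicates 1, 2 and 3 gave 212, 312 and 513, high-fat tea replicates 2 and 3 gave 332 and 260, and high-fat tea replicate 5 gave 2017. Of 40 calls of genes that the naming rule takes, 28 ended without at least 1 library and 36 with only the groups compared.

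The comparison of tea with water in chow-fed mice gives the change with tea on the standard diet. Only clock genes and a few others were called. The hour of collection is not given in the sources used here. A difference in hour between these 2 groups can therefore not be told apart from a change of the clock genes with tea. Dbp rose from 2.77 ± 0.687 to 9.02 ± 1.68 CPM (log2 1.70, SE 0.21, adjusted p = 0.00352) and Nr1d1, the clock repressor REV-ERB alpha (chromosome 11, 98658758 to 98666159, minus strand), from 49.0 ± 13.0 to 154 ± 29.6 CPM (log2 1.65, SE 0.21, adjusted p = 0.00374). Fbxl9 rose from 3 ± 0.354 to 6.25 ± 0.736 CPM (log2 1.06, SE 0.18, adjusted p = 0.0472) and Hnrnpc, an RNA-binding protein with many processed copies, fell from 142.9 ± 17.9 to 93.9 ± 8.21 CPM (log2 −0.61, SE 0.09, adjusted p = 0.0157). Vmn2r1, a pheromone receptor of a large family named after its values were seen, rose from 0.255 ± 0.0757 to 1.01 ± 0.207 CPM (log2 1.96, SE 0.30, adjusted p = 0.0183). In each of these 5 genes the libraries of the groups did not overlap.

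Of 18 clock genes 2 rose and 0 fell (4 and 0 adjusted over the list alone; median 0.20, adjusted p = 0.00257, adjusted p = 0.987 with an estimated correlation), and the list's call ended with only the groups compared and without 9 libraries. Of 20 proliferation genes none was called (13 lower adjusted over the list alone; median −1.60, adjusted p = 0.000141, adjusted p = 0.987 with an estimated correlation). This list was highest in chow water replicate 1, the library with pancreatic transcripts, where Mki67 reached 63.0 CPM, and without that library its median was −0.08 and its call ended. The pancreas acinus list (median −13.03, 0 called, 12 lower adjusted over the list alone; adjusted p = 0.00757, adjusted p = 0.987 with an estimated correlation) followed the same library and its call ended without it. Lep was at 7.13 ± 6.83 CPM with tea and 58.9 ± 64.3 CPM with water (log2 −3.05, adjusted p = 0.27; −2.12 without chow water replicate 5 and −3.71 without chow tea replicate 2), and Trem2 was not called (log2 1.13, adjusted p = 0.426). Nor were Itgax (log2 −1.55, adjusted p = 0.372; −0.33 without chow water replicate 1), Tnf (log2 −0.95, adjusted p = 0.649), Ccl2 (log2 0.41, adjusted p = 0.838) and Adipoq (log2 0.20, adjusted p = 0.893). The same holds for Scd1 (log2 0.28, adjusted p = 0.907), Col1a1 (log2 0.09, adjusted p = 0.963), Adgre1 (log2 0.02, adjusted p = 0.995) and Pparg (log2 0.02, adjusted p = 0.993). Fasn (adjusted p = 0.971) and Ucp1 (adjusted p = 0.993) were not called either, and stood at 0.99 and 0.83 without chow water replicate 4. Ucp1 stood at −0.51, with the sign turned, without chow tea replicate 2.

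In all, 5 genes were called by edgeR's quasi-likelihood test and 2634 had an unadjusted p below 0.05. The libraries did not overlap in 545 genes (2.56%, where chance gives 0.79%). With only the groups compared edgeR called 0 genes (2398 at an unadjusted p below 0.05), DESeq2 called 260 and limma voom 14. The count was 9 without 3 libraries with other-organ transcripts and 0 without 9 (1501 at an unadjusted p below 0.05), settings chosen after seeing the data, 3 without chow water replicate 3, and 2 without any one of chow water replicates 2 and 4 and chow tea replicates 1, 4 and 5. Fbxl9 lost its call whichever of the 10 libraries was left out, with log2 changes from 0.97 to 1.11. Hnrnpc lost its call without chow water replicates 2 or 4 or chow tea replicates 1, 4 or 5, with log2 changes from −0.67 to −0.55 over all libraries left out.

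In tea-drinking mice, clock genes were among those that changed between high-fat and chow feeding. Dbp rose from 9.02 ± 1.68 to 66.9 ± 17.0 CPM (n = 5 per group, log2 2.89, SE 0.22, adjusted p = 1.56e-06). Npas2 fell from 26.5 ± 11.4 to 1.78 ± 0.469 CPM (log2 −3.90, SE 0.36, adjusted p = 2.29e-05) and Arntl, the core clock activator BMAL1 (chromosome 7, 112806672 to 112913333, plus strand), from 24 ± 8.39 to 3.15 ± 0.842 CPM (log2 −2.93, SE 0.31, adjusted p = 0.000127). Of 18 clock genes 6 rose and 3 fell (11 and 5 adjusted over the list alone; median 0.65, adjusted p = 0.0117, adjusted p = 0.603 with an estimated correlation), among them Ciart (log2 2.81, SE 0.42) and Bhlhe41 (log2 2.33, SE 0.33). The list's call ended without chow tea replicate 3. Bhlhe40 (log2 2.02, SE 0.39) and Tef (log2 1.28, SE 0.23) were called with all libraries and lost their calls without any one of chow tea replicates 1, 3, 4 and 5 and high-fat tea replicates 1 and 2, Bhlhe40 also without high-fat tea replicate 4 (log2 from 1.70 to 2.22 over the libraries left out for Bhlhe40 and from 1.16 to 1.39 for Tef).

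Outside the clock, Apmap, an adipocyte membrane protein, fell by 1.73 on the log2 scale (SE 0.27, adjusted p = 0.013), Scd3, a desaturase with near-identical relatives, fell by 3.47 (SE 0.62, adjusted p = 0.0237) and Smim41 fell by 2.76 (SE 0.54, adjusted p = 0.0387). The calls of Scd3 and Smim41 ended without any one of chow tea replicates 1 and 5 and high-fat tea replicates 1, 2 and 5, that of Smim41 also without chow tea replicate 4. Lep was 7.13 ± 6.83 CPM on chow and 255.4 ± 388.5 CPM on the high-fat diet (log2 5.16, SE 1.20, adjusted p = 0.0792), called without 3 libraries with other-organ transcripts (adjusted p = 0.0407) and without high-fat tea replicate 3 (adjusted p = 0.0172). It was at 3.55 and not called without high-fat tea replicate 5, and at 5.83 without chow tea replicate 2. Mmp12 (log2 3.85, adjusted p = 0.0638), Cyp2d22 (log2 −1.03, adjusted p = 0.0591) and Trem2 (log2 0.51, adjusted p = 0.698) were not called. Nor were Itgax (log2 2.05, adjusted p = 0.182; 1.08 without high-fat tea replicate 5), Fasn (log2 −1.90, adjusted p = 0.229; −3.19 without high-fat tea replicate 2), Scd1 (log2 −1.09, adjusted p = 0.364) and Pparg (log2 −0.39, adjusted p = 0.589). Also not called were Tnf (log2 0.81, adjusted p = 0.619), Adipoq (log2 −0.27, adjusted p = 0.77), Ccl2 (adjusted p = 0.774), Col1a1 (log2 −0.08, adjusted p = 0.943), Adgre1 (adjusted p = 0.944) and Ucp1 (log2 −0.28, adjusted p = 0.954; 0.34 without chow tea replicate 2 and −0.93 without high-fat tea replicate 2). Mmp12 stood at 2.18 without high-fat tea replicate 5 and at 4.65 without chow tea replicate 1, and was called without high-fat tea replicate 3 (adjusted p = 0.0122), as was Cyp2d22 (adjusted p = 0.0244). Of 20 lipid-associated macrophage genes 0 were called (2 higher adjusted over the list alone; median 0.36, adjusted p = 0.423). None of the 21 drug metabolism genes was called (1 higher and 2 lower adjusted over the list alone), with a median of −0.12, a mean of 0.024 and a lower direction by camera (adjusted p = 0.0117, adjusted p = 0.568 with an estimated correlation). Branched-chain amino acid breakdown (median −0.17, 0 called, 5 lower adjusted over the list alone) and de novo lipogenesis (median −0.17, 0 called, 2 lower adjusted over the list alone) were called by camera (both adjusted p = 0.00395, adjusted p = 0.975 with an estimated correlation), the former not without high-fat tea replicate 5 and the latter not without 9 libraries.

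By edgeR's quasi-likelihood test 38 genes were called, 8 higher and 30 lower, and 3482 had an unadjusted p below 0.05. The libraries did not overlap in 591 genes (2.77%, where chance gives 0.79%). The count was 292 without 3 libraries with other-organ transcripts (all 38 among them) and 5 without 9, settings chosen after seeing the data, 5 with only the groups compared, 935 with DESeq2 and 319 with limma voom. Left out in turn, chow tea replicates 1, 4 and 5 gave 11, 20 and 10, high-fat tea replicates 1 and 5 gave 14 each, and high-fat tea replicate 3 gave 390.

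**Figure D3:**
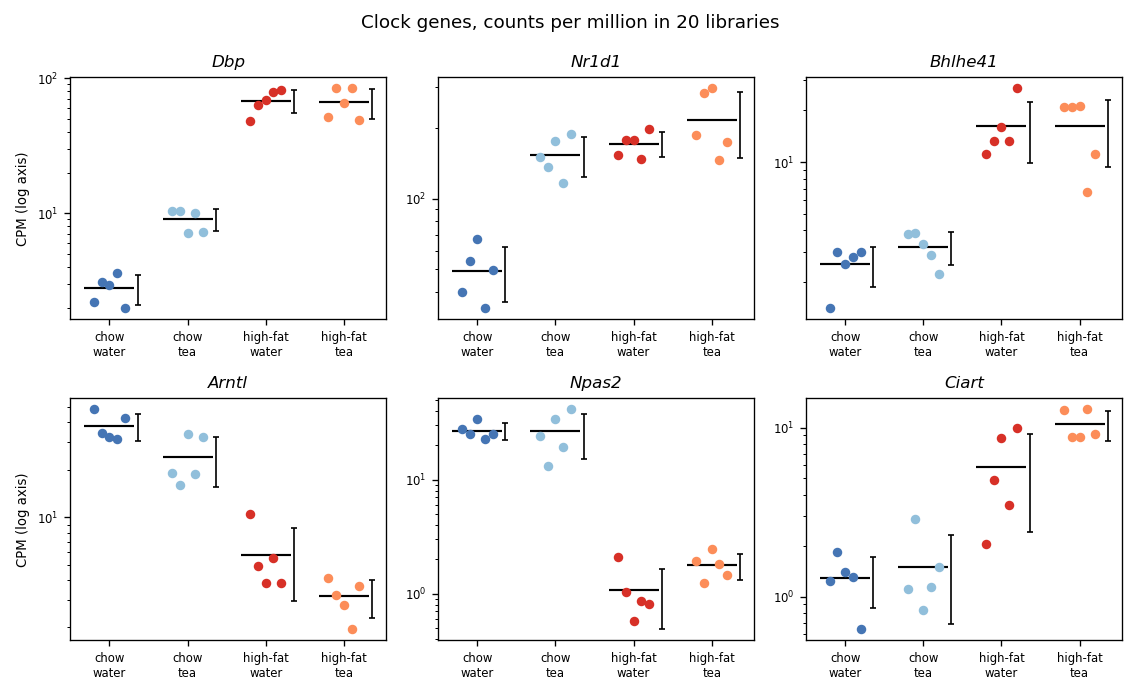
Levels of 6 clock genes (CPM, log axis) in the 4 groups. Dots are single libraries, the horizontal line is the mean of 5, and the bar at the right is the SD, whose lower arm is left out where it would reach 0 or below. Dbp stood at 2.77 ± 0.687 CPM with chow and water, 9.02 ± 1.68 with chow and tea, 68.3 ± 13.4 with the high-fat diet and water and 66.9 ± 17.0 with the high-fat diet and tea.

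The interaction tests whether the change with tea differed between the diets. Scd2 had the lowest p (log2 difference −2.95, SE 0.35, adjusted p = 0.00238), with a change with tea of −1.94 on the high-fat diet and of 1.01 (not called, adjusted p = 0.187) on chow. Rassf6 (log2 3.52, SE 0.50, adjusted p = 0.00946) and Septin9, a cytoskeletal GTPase (log2 −1.21, SE 0.16, adjusted p = 0.00616), were also called, and these 3 stayed called whichever library was left out. Dbp (log2 −1.73, SE 0.29, adjusted p = 0.0291) was called lower in the clock list, of which 1 gene was higher and 1 lower (1 and 3 adjusted over the list alone; median −0.16, adjusted p = 0.587). Trem2 (log2 −3.54, adjusted p = 0.107), Lep (log2 0.39, adjusted p = 0.935) and Nr1d1 (log2 −1.31, adjusted p = 0.107) were not called, so for these genes the change with tea was not shown to differ between the diets. Adgre1 (log2 −1.42, adjusted p = 0.239), Ccl2 (log2 −1.60, adjusted p = 0.374), Col1a1 (log2 −0.91, adjusted p = 0.428) and Itgax (log2 −1.15, adjusted p = 0.624; −2.34 without chow water replicate 1 and −2.13 without high-fat tea replicate 5) were not called. Adipoq (log2 −0.38, adjusted p = 0.789), Ucp1 (log2 −1.21, adjusted p = 0.86; −1.94 without chow water replicate 4), Pparg (log2 0.23, adjusted p = 0.869), Scd1 (log2 −0.40, adjusted p = 0.873), Tnf (log2 −0.45, adjusted p = 0.887; 0.16 without high-fat water replicate 1) and Fasn (log2 −0.39, adjusted p = 0.906; −1.67 without high-fat tea replicate 2 and −1.23 without chow water replicate 4) were not called either. Ucp1 also stood at −1.86 without high-fat tea replicate 2 and at −0.60 without chow tea replicate 2. Trem2 was called without high-fat tea replicate 5 (log2 −4.10, adjusted p = 0.0305). The value of Lep ranged from −1.22 without high-fat tea replicate 5, with the sign turned, to 1.06 without chow tea replicate 2. Dbp lost its call without 12 of the 20 libraries left out in turn.

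As groups, lipid-associated macrophage genes had a lower interaction (median −1.07, 0 of 20 called, 5 lower adjusted over the list alone; adjusted p = 1.43e-08, adjusted p = 0.341 with an estimated correlation). Drug metabolism genes had a higher one (median 0.56, 0 of 21 called, 1 higher adjusted over the list alone; adjusted p = 0.000645, adjusted p = 0.177 with an estimated correlation). The pancreas acinus list was also called (median 12.77; 12 higher adjusted over the list alone; adjusted p = 9.07e-05, adjusted p = 0.719 with an estimated correlation), is highest in chow water replicate 1, and without that library had a median of −0.27 (not called, adjusted p = 0.31). By edgeR's quasi-likelihood test 14 genes were called, 7 higher and 7 lower, and 3196 had an unadjusted p below 0.05. The count was 44 without 3 libraries with other-organ transcripts (12 of the 14 among them) and 0 without 9 (2260 at an unadjusted p below 0.05), settings chosen after seeing the data, 692 with DESeq2 and 84 with limma voom. Leaving out 1 library gave counts from 3 to 111, the last without high-fat tea replicate 5, and only high-fat water replicate 4 and high-fat tea replicate 4 left it near 14, at 12 and 16. Of 10 calls of genes that the naming rule takes 7 ended without at least 1 library.

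The changes with tea in high-fat-fed mice ran opposite to those with the diet. Of the 3232 genes called for diet in water-drinking mice, 3137 (97.1%) had the opposite sign with tea, and 759 were called in both comparisons, all of them in opposite directions. Of these, 422 rose with the diet and fell with tea, where independent lists would share 39.4. The other 337 fell and then rose, where independent lists would share 31.2. The lists are not independent, as both comparisons use the same high-fat water libraries. That sharing can by itself add genes called in opposite directions, and how many it adds was not computed. Over all 21306 genes the share was 77.4%. The shared libraries alone give opposite signs. In 20 simulations with unchanged groups the share over all genes was 66.5%, and with a diet effect and no tea effect it was 65.6% of called genes (63.1% to 67.4%). With the shared libraries split so that no library entered both comparisons, the share was 92% of called genes on average over 20 splits, from 81.5% to 97.6%. Across genes, which are not independent replicates, the correlation of fold changes was −0.70 (−0.50 simulated) and the covariance −1.23 (−0.22 simulated for unchanged groups). Other-organ genes enter both values, and their weight was not tested. Over the called genes the slope of the tea change on the diet change was −0.46. Resampling of the called genes outside the clock list, not of mice, gave −0.51 to −0.42. The shared high-fat water libraries alone give a negative slope, and no slope was computed with these libraries split.

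**Figure D4:**
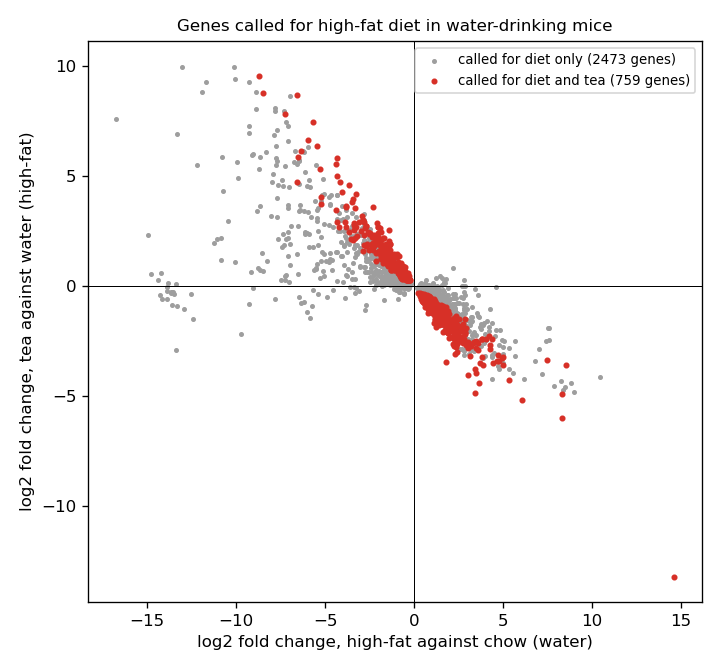
Log2 fold change with tea in high-fat-fed mice against log2 fold change with the high-fat diet in water-drinking mice, 1 dot per gene called for diet. Of the genes called for diet, 2473 were called for diet alone and 759 in both comparisons, and all 759 have opposite signs. Both axes use the same high-fat water libraries, which alone gives a negative relation.

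Comparisons that share no library were set side by side as well. Of the 3232 genes called for diet in water-drinking mice, 2626 (81.2%) changed in the same direction in tea-drinking mice and 28 were called in both, and 37 of the 38 genes called in tea-drinking mice (97.4%) had the same direction in water-drinking mice. Across all genes these diet changes had a correlation of −0.10, and 0.063 across the 3232 genes, with a slope of 0.016. Across the 38 genes the correlation was 0.89, and the slope of the change in water-drinking mice on that in tea-drinking mice was 0.85. The 3232 include pancreas genes that rested on chow water replicate 1, such as Clps (−13.91) and Try5 (−14.77). Their weight in these values was not tested. Genes are not independent replicates. Of the 928 genes called for tea in high-fat-fed mice, 670 (72.2%) had the same direction in chow-fed mice and 2 were called in both. The correlation of the tea changes was −0.19 across all genes and 0.029 across the 928, with a slope of 0.009. Of the 5 genes called in chow-fed mice, 4 had the same direction on the high-fat diet.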

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

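The counts of splits of the libraries were planned before their results were seen, and the other tests in this part were chosen after the patterns had been seen.

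Some clock genes separated high-fat from chow libraries. Of 18 clock genes 8 (Arntl, Clock, Npas2, Nr1d2, Dbp and Bhlhe41 among them, and Per3, named after its values were seen) separated all 10 chow from all 10 high-fat libraries without overlap, against 0.19% of all genes and 0.00108% by chance. RNA of other tissues does not account for it, since without the 9 libraries that hold such RNA the list's median absolute log2 change between the water groups went from 1.49 to 1.33, or 88.9% of its value. Collection of chow and high-fat mice at different hours would separate these 8 genes as well, and it cannot be told apart from an effect of the diet, because the hour of collection is not given in the sources used here. An effect of the diet on the clock of the tissue, which the design names, stays open beside it and was not tested further.

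Changes with tea opposed those with the diet in high-fat-fed mice. The high-fat water libraries shared by both comparisons cannot be the whole cause, since the share of opposite signs was at least 81.5% in each of 20 splits in which no library was shared. A shift in the hour of collection would carry the clock genes along. Yet their tea change had a slope of 0.008 on their diet change (−0.15 to 0.23 by resampling of genes). Of 14 clock genes called for diet, 4 had the opposite sign. A chow library labelled as high-fat tea replicate 3 was tested because that library had little leptin (5.06 CPM), and it lay nearer the chow mean in 1 of the 8 separating clock genes (12.5%). A weaker response to the high-fat diet in mice that drank tea, as the design would give, may therefore be a candidate explanation, although body weight and food intake are not used here and the count of tea calls rested on single libraries.

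Transcripts of other organs stood in single libraries. In the pancreas acinus list (chow water replicate 1) and the kidney list (high-fat tea replicate 4), both written before the data were examined, 100% of members (13 and 10) lay over 20 times above the median of the other libraries, which is consistent with tissue of those organs in the dissected sample. For high-fat water replicate 4 this test cannot decide. Lists for the seminal vesicle, adrenal cortex and adrenal medulla were made only once its genes had been looked at. Their high shares were fixed by that choice. The transcripts themselves stood in this library, with Svs5 at 18850 CPM against at most 1.78 CPM in any other. The epididymis and testis list, written before the data were examined, took reads there as well, but its members were not tested in this way. The most abundant genes, named after their values were seen, were Pnlip and Ctrb1, Kap and Slc34a1 (3767 CPM), and Svs5, Semg1 (17490 CPM), Star and Chgb (2145 CPM) in these 3 libraries. Exchange of reads between libraries stays open. The kidney share of the other 19 libraries differed 1559-fold, but the highest (chow water replicate 2) held kidney transcripts. No biological explanation was tested.

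For each comparison, 100 splits of its libraries into groups of the same sizes were drawn (of 126 possible, and 31752 for the interaction), the real one included. For diet in water only the real split gave a count that large (3232 genes against at most 504). The same held for tea in high-fat feeding (928 against 798), tea in chow (5 against 0) and diet in tea (38 against 3). A share of 1 in 100 is the lowest that these splits can reach, and 5 comparisons were tried. Chance is therefore unlikely for these counts but not excluded. For the interaction 4 of 100 splits gave as many (14 in the real one). Its splits exchanged tea and water within each diet, which takes away any change with tea. They can therefore not test whether that change differed between the diets. The highest other split called 526 genes, many times the real 14, and the 798 of tea in high-fat feeding is close to the real count. Which libraries were exchanged in these splits was not examined, and the cause of their counts was not tested.

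Within groups, single libraries stood apart from the other 4 in 113 of 556 groups of 5 tested for genes and lists named here (20.3%). Their gap to the nearest library exceeded 0.71 of the group's range. Chance gives about 1 in 20 only for normal values, which CPM were not shown to be. Some of these genes were named for standing high in single libraries, which raises the share. High-fat tea replicate 4 had 19, and high-fat water replicate 1 also 19. In high-fat tea replicate 4 the highest values of its group were those of Kap (14000 CPM), Slc34a1 (3770), Ces1f (1120), Umod (1070), Cyp4a10 (835), Pigr (245), Rdh16 (197), Guca2b (162), Gsr (155), Gsta2 (122), Nqo1 (77.4), Scnn1g (35.8), Cela1 (30.3), Glt1d1 (27.0), Acot3 (15.3) and 4732463B04Rik (5.12), the kidney list at 9.03 and the NRF2 list at 7.24 (mean log2 of CPM plus 1), and Pparg was lowest (59.9). In high-fat water replicate 1 the highest were Lgals3 (930), Gpnmb (863), Mmp12 (294), Oxtr (200), Ubd (186), Itgad (125), Trem2 (101), Saa3 (68.4), Tph2 (52.6), Il1rn (47.7), Vsig8 (40.2), Ccl2 (18.4), Arntl (10.6), Pnlip (5.95), Ctrb1 (5.70), Tnf (1.64), Clps (0.991), Try5 (0.832) and the pancreas list (2.04).

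In chow water replicate 1 the highest were Pnlip (95800), Ctrb1 (83800), Cela1 (68400), Try5 (24900), Clps (19400), Pigr (1230), Guca2b (406), Lgals3 (133), Chgb (119), Btnl6 (115), Mki67 (63.0), Itgax (18.5), the pancreas list (14.9) and the proliferation list (4.15), and the lowest Pck1 (3000), Aldh6a1 (333), Bhlhe41 (1.40) and the list of branched-chain amino acid breakdown (6.4). In high-fat tea replicate 5 the highest were Lep (943), Npr3 (763), Pgd (258), Gpnmb (223), Lgals3 (206), Mmp12 (56.9), Oxtr (27.4), Itgax (23.2), Ubd (17.0), Vsig8 (7.52), Itgad (5.92), Semg1 (1.79), Svs5 (1.78) and Tph2 (1.02). In high-fat water replicate 4 they were Svs5 (18900), Semg1 (17500), Star (5750), Chgb (2150), Nr4a2 (327), Ptgs2 (56.8), Kap (25.1), Slc34a1 (7.42), Umod (0.429), the immediate early list (6.46) and the kidney list (1.40).

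The remaining libraries had at most 6 such values each. They were Kap (910), Slc34a1 (290), Cyp4a10 (161), Umod (124), Gsta2 (34.2) and Atp6v0d2 (4.69) in chow water replicate 2, Fasn (9740), Pdk1 (149) and Atf3 (13.3) in chow water replicate 4, Lep (170), Sfrp5 (59.3) and Oxtr (10.5) in chow water replicate 5, Umod (39.9) and Gsta2 (7.97), with Pck1 (4670) and Nr1d2 (56.4) lowest, in chow tea replicate 3, Mmp12 (2.88) and Semg1 (0.0872) in chow tea replicate 1, Bhlhe40 (18.9) and Saa3 (11.8) in chow tea replicate 2, Wfdc2 (6.45) and Clps (0.972) in chow tea replicate 4, and Sfrp5 (50.7) and Btnl6 (0.955) in chow tea replicate 5. In high-fat libraries they were Nqo1 (12.9) and Fbxl9 (3.40) in water replicate 5, Gbp3 (45.9) in water replicate 2, Fasn (3530), Star (216) and Chgb (2.03) in tea replicate 2, and Cyp2e1 (10000) and Eif4ebp3 (3.26) in tea replicate 3.

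The change with tea differed between the diets in 14 genes by the interaction test of edgeR. The log2 differences (tea change on the high-fat diet minus that on chow) of those reported here were 3.52 for Rassf6, 3.02 for Eif4ebp3, 2.93 for 4732463B04Rik, 2.36 for Acot4, 1.41 for Ivns1abp, 0.95 for Sqor, −0.99 for Ano8, −1.06 for Vac14, −1.21 for Septin9, −1.73 for Dbp, −2.69 for Krt79, −2.95 for Scd2 and −3.95 for Rnase2a. Of these Eif4ebp3, 4732463B04Rik, Ano8 and Rnase2a were named after their values were seen. In the 20 fits without a library, the calls of Sqor and Ivns1abp ended in 17 each, that of Krt79 in 16, Vac14 in 15, Acot4 in 13 and Dbp in 12, and those of Rassf6, Scd2 and Septin9 in 0. The exons of 4732463B04Rik overlap Acot4 on the opposite strand, and 67.3% of the exonic bases of Eif4ebp3 overlap Maskbp3, so these values are not independent of their neighbours. Among reads that the tests did not use, high-fat water replicate 4 held 6.16% of its reads in genes removed by the filter on low counts, against at most 1.38% in any other library (chow water replicate 1).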

How the results depend on the processing

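Dropping 2, 3 or 9 libraries, halving the reads and adding covariates for other tissues were chosen after the data had been seen, and the other alternatives were planned before.

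Across all alternatives, 5716 values of single genes and lists kept their direction and their side of the threshold (uncalled values that changed sign among them), 699 were no longer called, 138 became called and 17 changed direction. Counts are given in the order diet in water, tea on the high-fat diet, tea on chow, diet in tea and interaction. With all 20 libraries they were 3232, 928, 5, 38 and 14. With DESeq2's RLE size factors in edgeR they were 3273, 972, 4, 36 and 14 (of the original calls 3084, 903, 4, 36 and 14 were shared), and with upper-quartile factors 3083, 821, 5, 35 and 12 (2860, 773, 5, 31 and 11 shared). Neither scaling moved the share of higher calls by more than 10 points, but both turned the balance. For diet in water 1718 higher and 1514 lower calls became 1570 and 1703 with RLE and 1382 and 1701 with upper-quartile factors, and for tea on the high-fat diet 439 and 489 became 505 and 467, and 431 and 390.

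Without a filter on low counts the last 4 counts were 408, 2, 19 and 4. DESeq2's own test gave 4401, 2444, 260, 935 and 692, limma voom with sample weights 5333, 2011, 14, 319 and 84, and 1 surrogate variable 3501, 1170, 5, 86 and 17. A fit of only the groups compared, whose spread comes from fewer libraries, gave 2678, 21, 0 and 5, and the unadjusted p was under 0.05 in 2398 genes for tea on chow. With an absolute log2 change of at least 1 they were 1604, 516, 4, 22 and 12, and at an adjusted p under 0.1 the diet in water gave 4945, tea on the high-fat diet 2289, diet in tea 208 and the interaction 46. Apart from the fit of fewer groups and the thresholds, the cause was not tested.

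Without the 2 libraries with pancreas and kidney transcripts the counts were 4665, 1711, 11, 195 and 34, and without 3 (also high-fat water replicate 4) 4546, 1602, 9, 292 and 44, of which 2708, 751, 5, 38 and 12 were among the original calls. Without 9 (also 6 with skeletal muscle transcripts), which leaves fewer libraries, they were 2052, 13, 0, 5 and 0, with 1390, 9, 0, 5 and 0 shared, and an unadjusted p under 0.05 in 1501 genes for tea on chow and 2260 for the interaction. Halved reads gave 3447, 1118, 5, 67 and 18, and covariates for pancreas, kidney and muscle 4544, 1478, 5, 760 and 34. The cause was not tested.

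Of 51 lists, camera called 17, 18, 11, 14 and 24 with its preset correlation, 1, 1, 0, 0 and 0 with an estimated correlation, and fry 8, 6, 0, 0 and 1. Upper-quartile factors gave 9 for diet in tea, and the fit of only the groups compared 11 for diet in water. For tea on chow 7 were called without 2 libraries, 6 without 3 and 7 with the covariates, and for the interaction 15 without 3. The cause was not tested.

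The share of genes called for diet in water with the opposite sign for tea on the high-fat diet was 97.1%. It was 97.9% with the surrogate variable, 98.0% without 3 libraries, 98.5% without 9, 92.0% on average with the high-fat water libraries split between the comparisons, and 77.4% over all tested genes. The diet change had the same sign in both drinks in 81.2% of calls, 82.9% without the filter, 79.8% with DESeq2, 86.1% with voom, 84.5% with only the groups compared, 89.4% with the surrogate variable, 87.8% without 2 or 3 libraries, 91.5% without 9 and 91.7% with the covariates. The tea change had the same sign on both diets in 72.2%, against 67.1% with DESeq2, 55.0% with only the groups compared, 75.9% with the surrogate variable, 61.5% without 9 and 75.1% with the covariates. The cause was not tested.

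Replicate numbers recur in all 4 groups without a stated meaning. Deviations from the group means correlated with a median of 0.014 (−0.27 to 0.475) over 30 pairs of the same number, 9 of them over 0.1, and −0.026 over 120 other pairs, and 5 of 20 libraries correlated best with one of their own number, so the libraries share only a number. With the number as a block the counts were 2611, 632, 2, 28 and 14, the share of opposite signs was 98.2% and that of the diet change with the same sign 85.4%.

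Some values changed direction. Cela1 fell with diet in water (log2 −9.27) but stood at 0.61 with voom, 1.25 without 2 libraries, 1.16 without 3, 1.81 without 9 and 1.46 with the covariates. Without 9, Clps (−13.91) stood at 3.43 and Try5 (−14.77) at 1.72. The median of the pancreas list for diet in water (−13.65) was −0.32 without 3, with camera's direction turned, and 3.16 without 9. For tea on chow (−13.03) it was −0.037 without 2 and −0.022 without 3, again with camera's direction turned, 2.64 without 9 and 0.99 with the covariates. These alternatives take out or model the library with pancreas transcripts, and voom with sample weights gave it a weight of 0.263. For tea on the high-fat diet the immediate early list (−0.75) was at 0.14 without 3, and Ptgs2 (−4.39) at 0.036 without 9, where high-fat water replicate 4, which holds its highest value, is gone.

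Leaving out each library in turn gave 1890 to 3445 calls for diet in water, 212 to 2017 for tea on the high-fat diet, 2 to 6 for tea on chow, 10 to 390 for diet in tea and 3 to 111 for the interaction. Lists called ranged from 15 to 20, 16 to 23, 5 to 17, 10 to 14 and 17 to 25, the share of opposite signs from 95.5% to 98.0%, that of the diet change with the same sign from 70.4% to 88.1% and that of the tea change from 63.4% to 79.7%. Cela1 for diet in water ranged from −9.58 to 1.25 and the pancreas list for tea on chow from −13.78 to −0.037, each highest without chow water replicate 1. Of the calls of genes that the naming rule takes, 19 of 66, 28 of 40, 2 of 4, 4 of 10 and 7 of 10 lost the call in at least 1 of these fits. In simulated counts of the same depth, 14.9%, 29.9%, 31.3%, 25.4% and 3.0% of genes with a 2-fold change were recovered, so smaller changes can be missed.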

Other observations

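The leptin correlations were chosen after the group results had been seen, and the lists below were picked after their tests.

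In water-drinking mice on the high-fat diet, 6 of 25 genes of pro-inflammatory cytokines and sensors rose and 0 fell (8 and 0 adjusted over the list alone; median log2 0.56, adjusted p = 0.0337, adjusted p = 0.74 with an estimated correlation), led by Il1rn, the interleukin-1 receptor antagonist (log2 4.24, SE 0.69, adjusted p = 0.00105), and Cxcl1, a neutrophil chemokine (log2 2.20, SE 0.61, adjusted p = 0.0223, not called without chow water replicate 2, 3 or 4). Interferon response genes rose in 3 of 22 cases (6 adjusted over the list alone; adjusted p = 0.00254, adjusted p = 0.768 with an estimated correlation), among them Gbp3 (log2 0.94, SE 0.24) and Oas1a (log2 0.81, SE 0.25, a call that ended in 7 of 10 tests without a library). Of 12 dendritic cell genes 5 rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 0.0495, adjusted p = 0.74 with an estimated correlation), with Batf3, a factor of cross-presenting dendritic cells, at 1.40 (SE 0.31). The pro-inflammatory call ended without high-fat water replicate 1, and the dendritic call without any one of chow water replicates 2, 4 and 5 and high-fat water replicates 1, 2 and 3. In triglyceride synthesis 2 of 15 genes rose and 2 fell (3 and 6 adjusted over the list alone; adjusted p = 0.117), with Pnpla3 higher (log2 2.24, SE 0.56) and Pck1, the enzyme of glyceroneogenesis, lower (log2 −1.64, SE 0.32). Among 16 genes of angiogenesis and hypoxia 2 rose and 3 fell (2 and 4 adjusted over the list alone; adjusted p = 0.0976 by camera), and both Egln3, an oxygen sensor (log2 −2.42, SE 0.45), and Pdk1, a kinase that restrains pyruvate entry (log2 −1.28, SE 0.18), fell.

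With tea on the high-fat diet, 3 of 25 pro-inflammatory genes fell (3 adjusted over the list alone; median −0.43, adjusted p = 0.02, adjusted p = 0.712 with an estimated correlation), with Il1rn at −2.66 (SE 0.64, not called in 6 of 10 tests without a library), and Batf3 fell by 1.49 (adjusted p = 0.0161, not called without high-fat water replicate 1) as 1 of 12 dendritic cell genes (5 adjusted over the list alone; adjusted p = 0.000151, adjusted p = 0.37 with an estimated correlation). The pro-inflammatory call ended without high-fat water replicate 1 or high-fat tea replicate 4. Of 20 immediate early genes 3 fell (5 adjusted over the list alone; adjusted p = 0.014, adjusted p = 0.712 with an estimated correlation). Ptgs2 (log2 −4.39, adjusted p = 0.0433) and Nr4a2 (log2 −4.04, adjusted p = 0.0334) were high only in high-fat water replicate 4 and stood at −0.47 and −1.10 without it, no longer called. Their calls ended in 6 and 5 of the 10 fits without a library. Atf3 fell by 2.46 (SE 0.56, adjusted p = 0.0231), a call that ended without high-fat water replicates 1 or 2 or high-fat tea replicates 2 or 3. The list's call ended without high-fat water replicate 4 or high-fat tea replicate 4. Of 20 NRF2 antioxidant targets 1 rose (6 higher and 2 lower adjusted over the list alone; adjusted p = 0.115), namely Gsr, glutathione reductase (log2 1.04, SE 0.28, adjusted p = 0.0433), at 0.45 and not called without 3 libraries and not called in 6 of 10 tests without a single library. Proliferation genes (median −1.07, 0 of 20 called, 0 adjusted over the list alone; adjusted p = 3.25e-05, adjusted p = 0.712 with an estimated correlation) and mitochondrially encoded transcripts (median 0.69, 0 called, 0 adjusted over the list alone; adjusted p = 0.00242, adjusted p = 0.712 with an estimated correlation) were called by camera alone.

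A hypothesis tested across mice was that libraries with more leptin transcript hold more lipid-associated macrophage transcripts, and a companion that they hold fewer drug metabolism transcripts. Over 20 libraries, with each value taken relative to its group mean, Lep and the macrophage list had Pearson's r = 0.55 (permutation p = 0.0398, Benjamini-Hochberg adjusted 0.0796 over 2 relations) and Spearman's rho = 0.586 (permutation p = 0.00998, adjusted 0.02). Without the 2 libraries farthest from the median of Lep, high-fat tea replicates 3 and 5, r was 0.437. Lep and the drug metabolism list had r = −0.143 (permutation p = 0.665, adjusted 0.665) and rho = −0.114 (permutation p = 0.67, adjusted 0.67), and r = 0.031 without the same 2 libraries. Each p came from 100000 permutations within groups, two-sided, and no correlation was computed within single groups, each of which holds 5 libraries. These values are consistent with a link between leptin and macrophage transcripts within groups by rank, but Pearson's r missed the threshold after adjustment, and the share of adipose tissue in each library may move both.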
